A study of Mus musculus with 72 samples.

How the data were processed

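Genomic DNA of 6 tm1a knockout lines and of wild-type mice was bisulfite treated and amplified, and the amplicons were gel-isolated, pooled and sequenced, per the labels' protocols and the series design text. Bisulfite turns unmethylated cytosines into uracil, read as thymine, while methylated cytosines stay. Libraries were made from the double-stranded amplicons with an RNA library kit entered at its adapter step, per the labels. The submitters' processing notes name Bowtie2 and Bismark, without versions, and the mm9 build. Island and LacZ reads were aligned separately, per the series design text. The deposited files list, for each CpG site, a percent methylation and counts of methylated and unmethylated calls, without a header. The deposited percent equalled the share of methylated counts in all 72 files, to within 5.68e-14. The counts are not normalized, and no step that removes duplicate reads is given in the sources used here. Amplification before sequencing means that reads are not independent molecules, and unequal amplification of methylated and unmethylated strands can shift a level.

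Libraries were grouped by the line, tissue, amplicon and genotype in their titles. Titles spell 2 of the lines in 2 ways, which were merged. The 3 Rgcc wild-type libraries carry the mapping accession of Rab32 in their labels, although their files list the same chromosome 14 positions as the Rgcc knockouts, and they were grouped by title. Gene symbols were matched through a table of GRCm38 RefSeq genes, used for names only. No files were identical.

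Rows within 2000 bp of the median position of a line's island were kept. The 249 rows elsewhere, at most 0.0343% of the calls of a library, were left out. Sites with at least 10 reads were used. The level of an island library was the unweighted mean percent over the sites covered in both libraries of a pair, and the level of a LacZ library the mean over the 141 sites covered in all LacZ libraries. Median coverage per site was 1050 to 238872 for islands and 3243 to 20419 for LacZ. Pooled levels had 95% Wilson intervals of at most 0.249 percentage points to either side. Non-CpG cytosines were not listed, so the planned share of unconverted cytosines was not computed and incomplete conversion was not measured directly. No strand was at hand, so the 2 sides of an island were set by increasing coordinate.

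Knockout and wild type were compared by two-sided exact sign-flip permutation tests over the 6 line means and over the tissues of each line, the latter with Benjamini-Hochberg adjustment over lines. Sums of squares between lines or tissues were tested with 100000 permutations, within lines for tissues. Correlations used exact pairings for 6 values and 100000 permutations within lines for 24, with Benjamini-Hochberg adjustment over 8 correlations. Site counts were tested with the quasi-likelihood model of edgeR 4.0.16 in R 4.3.3, on methylated and unmethylated counts with tissue and genotype terms, at an adjusted p of 0.05 over the sites of a line. The limma 3.58.1 test on logit methylation (offset of 0.5 calls) was an alternative. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 were used for the rest.

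Named sites were, for each island, those with the largest and smallest mean difference over tissues, and for LacZ those with the highest and lowest mean level in each line, among sites with at least 10 reads in every library of the line. This rule, the tests and most alternatives were fixed before the data were examined. The alternatives were no coverage minimum, a minimum of 100 reads, pooled reads, the median over sites, log2 odds with an offset of 0.5 points, sites covered in every library of a line, leaving out each tissue pair or line, and, for the site test, no tissue term, limma and a difference of at least 10 points. Leaving out 2 kinds of sites together was chosen after seeing the data, as were sites covered in every library for the tissue tests and correlations. Elevated sites were island sites with a wild-type median of at least 5%, whether or not the genotypes differed there, and near-constant sites were LacZ sites with an SD below 7 points over the 24 libraries. A rule on the mean of the knockout and wild-type medians, and both rules at sites covered in every library, were added later for the island difference.

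The site test was tested on simulated data, with beta-binomial counts at the real coverages and site means (overdispersion 0.002, 10 simulations per line and setting) and 33.3% of the sites changed, rounded to whole sites. For an odds ratio of 4 it recovered 98.0% of changed sites in Arap, 94.2% in Dstn, 86.7% in Lyplal1, 92.8% in Ninj1, 18.5% in Rab32 and 84.1% in Rgcc. For an odds ratio of 2 it recovered 47.0%, 7.69%, 55.6%, 44.4%, 5.38% and 1.82% in the same order. Unchanged sites made up more of the calls than the 5% aimed at in Arap (6.0% and 10.9% for odds ratios of 2 and 4), Lyplal1 (19.4% and 9.3%) and Rab32 (30.0% and 7.69%). With no site changed, at most 0.5% of sites were called in any line. The simulated sites were drawn independently, without tissue effects or shifts shared by the sites of a library. These rates therefore need not hold for the real data.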

Results

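DNA methylation was measured by bisulfite amplicon sequencing in 6 mouse knockout lines on a C57BL/6N background, at 7 weeks of age. Each line carried a tm1a allele of the Knockout Mouse Project, in which the native promoter drives a LacZ reporter and a neo selection cassette is present. The targeted genes were Arap (its label accession belongs to Arap1, a GTPase-activating protein), Dstn (destrin, an actin-depolymerizing protein), Lyplal1 (lysophospholipase-like 1), Ninj1 (ninjurin 1), Rab32 (a small GTPase) and Rgcc (regulator of cell cycle). For each line and tissue there were 3 libraries, covering the promoter CpG island in the knockout, the LacZ sequence in the same knockout DNA, and the island in wild type. Arap had 5 tissues, Dstn 6, Lyplal1 2, Ninj1 6, Rab32 2 and Rgcc 3, which gave 24 combinations of line and tissue and 72 libraries. There was 1 library per line, tissue and amplicon in each genotype, so tissues served as the replicates of a line. The labels do not say whether tissues came from the same animals or from pools, and p-values within a line measure the spread between tissues.

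The 48 island libraries held between 80680 and 7665657 methylation calls, with a median coverage per CpG site of 1050 to 238872. The 24 LacZ libraries held between 494076 and 3898035 calls, with a median coverage of 3243 to 20419. The widest 95% Wilson interval of a library's pooled level extended 0.249 percentage points to either side for islands and 0.137 for LacZ. The levels below are unweighted means over sites, whose widest 95% margin from counting was 0.722 points for islands and 0.155 for LacZ if sites erred independently, and 2.01 and 1.77 if the sites of a library erred together. These values cover counting error only, because PCR reads without molecular identifiers are not independent molecules. In mm9 coordinates, the sites covered by at least 10 reads in every library of a line lay on chromosome 7 from 108496480 to 108496701 for Arap (31 sites) and on chromosome 2 from 143740490 to 143741399 for Dstn (78 sites). They lay on chromosome 1 from 187940948 to 187941221 for Lyplal1 (28 sites) and on chromosome 13 from 49282886 to 49283487 for Ninj1 (55 sites). They lay on chromosome 10 from 10277589 to 10277983 for Rab32 (40 sites) and on chromosome 14 from 79700866 to 79701694 for Rgcc (67 sites). The labels call these regions promoter CpG islands, and their exons and transcription start sites were not annotated here. In LacZ, 141 sites from position 150 to 2896 of the reporter reference were covered in all 24 libraries.

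Promoter island methylation was first compared between knockout and wild type. The Lyplal1 island had a mean level of 14.2% ± 3.39 (SD, n = 2 tissues) in knockouts and 7.51% ± 0.542 (SD, n = 2) in wild type, a difference of 6.69 ± 2.85 percentage points. The Rgcc island had 8.62% ± 0.672 (SD, n = 3) in knockouts and 6.61% ± 0.139 (SD, n = 3) in wild type, a difference of 2.01 ± 0.543 points. In Lyplal1 the knockout exceeded wild type by 8.71 points in kidney and 4.68 in liver, and in Rgcc by 2.47 points in heart, 1.41 in lung and 2.15 in muscle. The other 4 islands had mean differences below 0.5 points in size, with 0.205 ± 0.622 (SD, n = 5) in Arap (0.0844 without brain and 0.466 without liver), 0.241 ± 0.186 (SD, n = 6) in Dstn, 0.390 ± 0.363 (SD, n = 6) in Ninj1 and -0.251 ± 0.0105 (SD, n = 2) in Rab32. The knockout was higher in 4 of 5 tissues of Arap, 6 of 6 of Dstn, 5 of 6 of Ninj1 and 0 of 2 of Rab32. The Ninj1 direction depended on how sites were weighted: pooled over reads the difference was -0.594 points, with wild type higher in 5 of 6 tissues, and with a minimum of 100 reads it was 0.132. All these levels include sites with a wild-type median of at least 5%, except in Arap, which had no such sites. Without them, a choice made after seeing the data, knockouts had 7.71% and wild type 0.894% in Lyplal1. In the same order, the levels were 3.34% and 1.06% in Rgcc and 0.468% and 0.425% in Dstn. They were 1.35% and 0.538% in Ninj1 and 0.852% and 0.580% in Rab32.

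Over the 6 lines the mean difference was 1.55 ± 2.64 percentage points (SD, n = 6 lines), positive in 5 of them, and did not pass a two-sided exact sign-flip permutation test (p = 0.125). Without Lyplal1 the mean was 0.519 (exact permutation p = 0.25). It was 1.14 with no coverage minimum (exact permutation p = 0.312) and 1.39 with pooled reads (exact permutation p = 0.375). Without the sites that already had a wild-type median of at least 5%, a choice made after seeing the data, the mean difference was 1.74 and all 6 lines were positive (exact permutation p = 0.0312). That rule looks at wild type alone, so it can favour a higher knockout. Without the sites whose knockout and wild-type medians averaged at least 5%, also chosen after seeing the data, it was 1.40 (exact permutation p = 0.0312, the lowest possible with 6 lines). With the median over sites in place of the mean it was 1.49 (exact permutation p = 0.0312). Within lines, exact sign-flip tests over tissues gave p = 0.438 in Arap, 0.0312 in Dstn, 0.5 in Lyplal1, 0.0625 in Ninj1, 0.5 in Rab32 and 0.25 in Rgcc. After Benjamini-Hochberg adjustment over the 6 lines the smallest of these exact values was 0.188. The adjusted test could not pass in any line, because its lowest possible value with these numbers of tissues is 0.0938. Unadjusted, the test cannot go below 0.0312 with 6 tissues, 0.0625 with 5, 0.25 with 3 and 0.5 with 2. With no coverage minimum the Arap difference was -0.328 and the Dstn difference 0.0501 (exact permutation p = 0.906), and with the median over sites the Dstn difference was 0.0164 (exact permutation p = 0.688). Without the sites with a wild-type median of at least 5%, the Dstn difference was 0.0428 (exact permutation p = 0.656), the Ninj1 difference 0.812 and the Rab32 difference 0.272. The Ninj1 value rested on sites covered in only some pairs, being 0.299 over sites covered in every library of the line (exact permutation p = 0.0938).

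**Figure D1:**
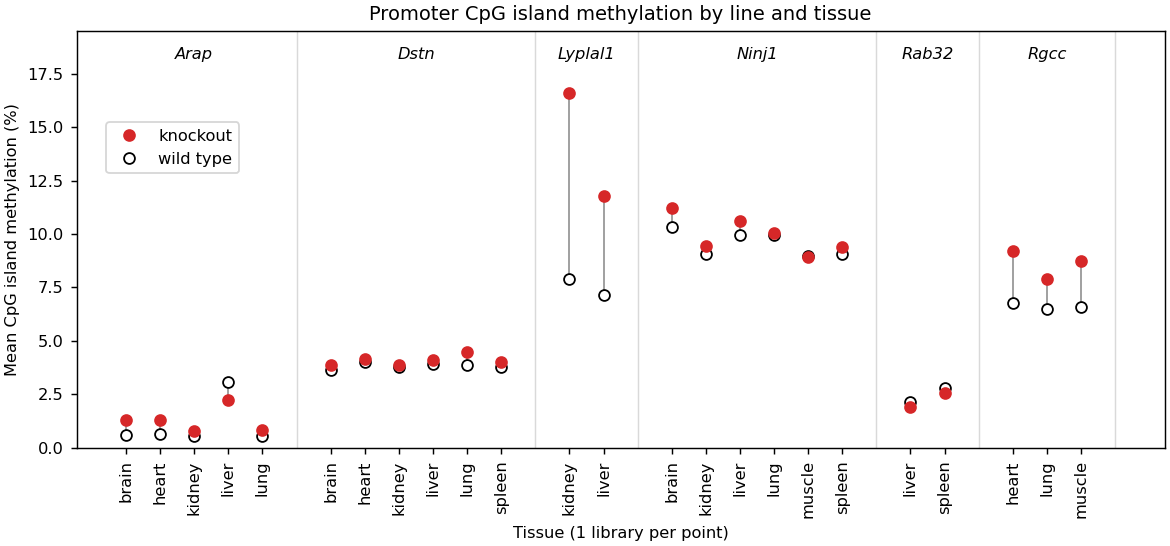
Mean methylation of the promoter CpG island (%, vertical axis) in each line and tissue (horizontal axis), with knockout as filled and wild type as open circles, 1 library per point. Both Lyplal1 tissues and all 3 Rgcc tissues have the knockout above wild type, and Arap liver has wild type (3.08%) above knockout (2.24%).

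The difference between genotypes was then tested at each CpG site, in edgeR's quasi-likelihood model with tissue as a term. In Lyplal1, 25 of 28 sites were higher in knockouts at an adjusted p under 0.05 and 0 were lower. They included all 23 sites with a wild-type median under 5%, whose differences ranged from 4.92 to 11.3 points and which were higher in both tissues. The Lyplal1 knockout libraries had a median coverage of 2312 in kidney and 2473 in liver, against 29809 and 23185 in wild type. In Rgcc, 27 of 67 sites were higher and 0 lower, each in all 3 tissues, with differences from 0.608 to 13.2 points. Of the 27 Rgcc sites, 25 were among the 33 sites on the lower-coordinate side of the middle of the amplicon. Coverage differed between the sides: 18 sites of the upper side had a lowest coverage of 81 to 178, of which 1 was called and 6 others gained at least 2.5 points without being called. The other 16 upper sites had a lowest coverage of 899 to 2198, and 1 was called. The site with the largest mean difference in Rgcc, at position 79700954, had 14.3% ± 1.47 (SD, n = 3) in knockouts and 1.04% ± 0.325 in wild type, at a coverage of at least 2095 (edgeR adjusted p = 0.000697). Only 1 site in Lyplal1 and 1 in Rgcc combined an adjusted p under 0.05 with a mean difference of at least 10 points.

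With all tissues included, the remaining lines had few differing sites. Arap had 5 of 31 sites higher and 0 lower, by 0.302 to 0.633 points, and the largest was at position 108496480, with 1.16% ± 0.5 in knockouts and 0.532% ± 0.0618 in wild type (n = 5, coverage at least 15451, edgeR adjusted p = 0.0285). The Arap count was set by single tissues, being 28 of 31 without liver (28 higher and 0 lower), 1 without brain and 0 without heart, kidney or lung. Median coverage in Arap was 19206 to 67885 in knockouts and 120951 to 238872 in wild type. Incomplete conversion was not examined for Arap. Ninj1 had 3 of 55 sites higher and 2 lower, and the count was 1 without brain, 3 without liver and 3 without a tissue term. At position 49282938 the Ninj1 knockouts had 0.326% ± 0.0929 and wild type 15.7% ± 1.13 (n = 6, coverage at least 12615, edgeR adjusted p = 2.78e-08), lower in each of 6 tissues. At position 49283393 the Ninj1 knockouts had 23.2% ± 7.08 and wild type 11.5% ± 1.09 (n = 6, coverage at least 18583, edgeR adjusted p = 0.0247). Rab32 had 5 of 40 sites higher and 2 lower, and 0 without a tissue term. The Rab32 site at position 10277673 had 6.60% ± 2.31 in knockouts and 21.4% ± 2.16 in wild type (n = 2, coverage at least 23153, edgeR adjusted p = 0.0101). The named Ninj1 and Rab32 sites were all elevated sites, with a wild-type median of at least 5%, and the cause of their differences was not tested. Dstn had 0 of 78 sites in edgeR and 0 in limma, while 1 of 70 sites with a wild-type median under 5% and 5 of 8 others had an unadjusted p under 0.05 in edgeR.

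Other sites at the ends of the range of differences did not pass the edgeR test. These were Arap 108496644 (-0.377 points), Dstn 143741033 (11.1) and 143740846 (-5.36), Lyplal1 187941131 (15.5) and 187941019 (-0.101), Rab32 10277894 (8.11) and Rgcc 79701694 (-4.70). Except for the Arap site, each had a wild-type median of at least 5%. The Rgcc site had a coverage of at least 81, and the others of at least 4166.

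**Figure D2:**
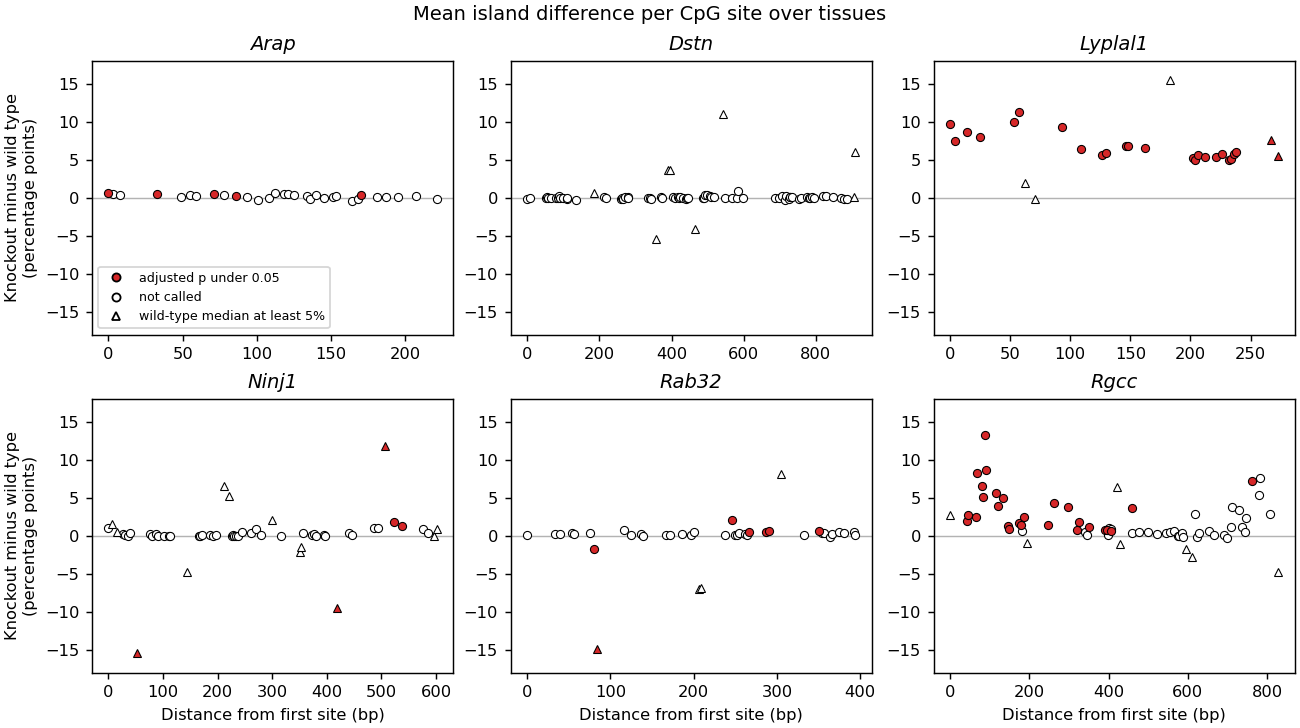
Mean knockout minus wild-type methylation over tissues at each CpG site (percentage points, vertical axis) against distance from the first site (bp, horizontal axis), 1 panel per line. Filled symbols had an edgeR adjusted p under 0.05 and triangles mark sites with a wild-type median of at least 5%; Lyplal1 sites called in the test all lie above 0, and 25 of the 27 called Rgcc sites lie before the middle of the amplicon.

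The size of the island difference varied between lines. Line accounted for 87.8% of the sum of squares of the 24 knockout minus wild-type differences (permutation p = 1e-05, the smallest that 100000 resamples can give). This test takes the tissues of a line as independent. It shows that differences were more alike within a line than between lines, and cannot separate the allele from animals or amplicons. Tissue differences were tested after centring on line means. Tissue accounted for 9.05% of the remaining sum of squares of knockout island levels (permutation p = 0.96) and 12.9% of wild-type island levels (permutation p = 0.941). With no coverage minimum these shares were 46.5% (permutation p = 0.0697) and 34.5% (permutation p = 0.229), and leaving out single pairs they ranged from 6.54% to 30.1% in knockouts and from 9.99% to 23.2% in wild type. The island difference above the middle coordinate of the amplicon minus that below it averaged 0.00562 points over lines (exact permutation p = 1, n = 6), and its sign changed under several settings.

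LacZ methylation was compared between lines at the same 141 sites. Averaged over all sites, the Dstn reporter had 61.3% ± 15.3 (SD, n = 6) and the Rgcc reporter 12.8% ± 3.39 (SD, n = 3). Lyplal1 had 48.8% ± 13.4 (SD, n = 2), Ninj1 40.4% ± 10.6 (SD, n = 6), Arap 36.9% ± 19.2 (SD, n = 5) and Rab32 18.9% ± 11.2 (SD, n = 2). Line accounted for 63.1% of the sum of squares of LacZ levels (permutation p = 0.00181), with the tissues of a line again taken as independent. The order of lines depended on the part of the reporter. From position 2629 to 2896, without near-constant sites, Dstn (17.3%) lay below Lyplal1 (44.7%), Ninj1 (39.1%) and Arap (37.7%). Levels also varied between tissues of a line. Arap ranged from 17.6% in brain through 28.0% in heart, 33.1% in kidney and 37.0% in lung to 68.6% in liver. Dstn had 71.1% in brain, 70.0% in heart, 68.8% in kidney and 73.0% in spleen, but 49.5% in liver and 35.6% in lung. Ninj1 had 25.8% in muscle, 29.7% in brain, 42.9% in spleen, 44.5% in lung, 45.2% in liver and 54.2% in kidney. Lyplal1 had 58.3% in kidney and 39.3% in liver, and Rab32 had 10.9% in liver and 26.8% in spleen. Rgcc had 14.0% in heart, 9.03% in lung and 15.5% in muscle. These levels include 14 near-constant sites, without which Rgcc had 9.86% in heart, 4.34% in lung and 11.5% in muscle, Rab32 6.56% in liver and 24% in spleen, and the line means were 62.3% in Dstn and 8.58% in Rgcc. After centring on lines, tissue accounted for 20.5% of the sum of squares, which did not pass the permutation test (p = 0.679), and 37.0% without Arap liver (permutation p = 0.269).

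**Figure D3:**
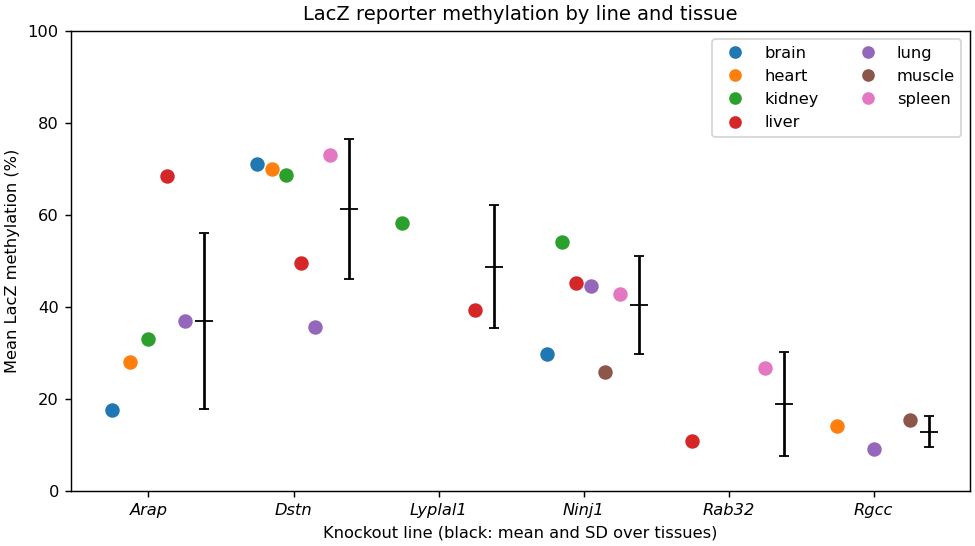
Mean LacZ methylation (%, vertical axis) of each knockout line (horizontal axis), with 1 point per tissue library and the mean and SD over tissues in black. Dstn reaches 73.0% in spleen, Arap spans 17.6% to 68.6%, and all Rgcc tissues lie at or below 15.5%.

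Along the reporter, the first part of the covered span (to position 1065) exceeded the last part of equal length (from position 1981) by 8.34 ± 8.78 percentage points (SD, n = 6 lines) in 5 of 6 lines, which did not pass the exact sign-flip permutation test (p = 0.0625). Without Dstn the difference was 5.32 points (exact permutation p = 0.125). In Dstn the first part had 69.6% ± 18.5 and the last 46.2% ± 7.33 (SD, n = 6). In Rab32 these were 26.1% ± 18 and 13.7% ± 4.94 (SD, n = 2), and in Rgcc 12.9% ± 2.80 and 15.0% ± 5.18 (SD, n = 3). In Rgcc the first part minus the last was -0.536 points in heart, -0.0413 in lung and -5.58 in muscle. The size of the Rgcc difference rested on muscle, without which the parts differed by -0.289 points on average. Without near-constant sites, Rgcc muscle had 24.5% from position 2198 to 2433 and 11.5% from 2629 to 2896. The levels of the first and last parts include near-constant sites. The first part minus the last was 3.14 points in liver and 21.7 in spleen of Rab32, and in Ninj1 it ran from -9.12 in liver to 15.7 in lung. The lowest LacZ site was position 156 in 5 lines, at 0% in Arap, Ninj1, Rab32 and Rgcc and 0.439% ± 1.07 (SD, n = 6) in Dstn. The least covered library at this site had 25 reads in Arap and 12 in Rgcc, where a count of 0 allows up to 12% and 25%. The highest site was position 2449 in Arap (98.8% ± 0.974), 956 in Dstn (88.8% ± 13.7) and 424 in Lyplal1 (79.6% ± 1.22). It was position 1633 in Ninj1 (80.6% ± 3.12), Rab32 (77.9% ± 4.59) and Rgcc (75.2% ± 10.5), where coverage fell as low as 12. In Lyplal1 the lowest site was position 462, at 30.7% ± 0.286 (SD, n = 2). Both named Lyplal1 sites, 424 and 462, were near-constant sites. Positions 156, 1633 and 2449 were not among the 141 sites covered in all LacZ libraries. In Lyplal1 only those 141 sites could be ranked, so its named sites are not comparable with those of the other lines.

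**Figure D4:**
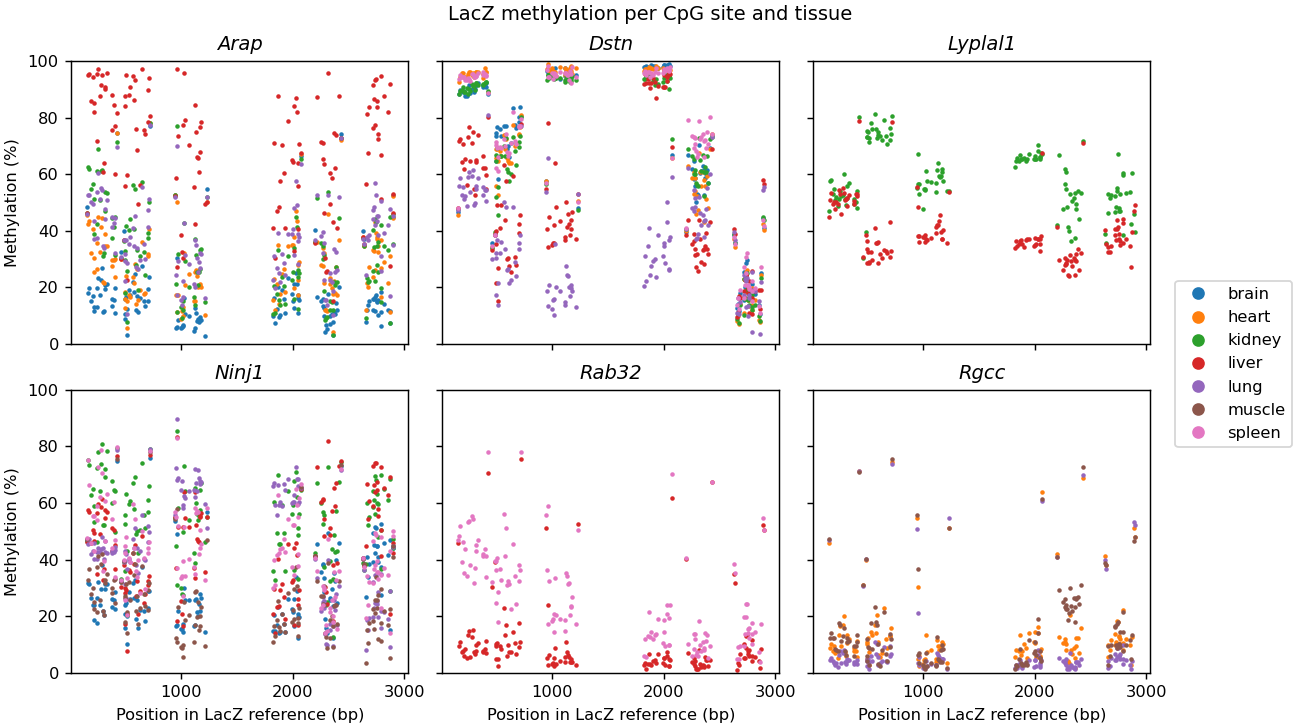
Methylation (%, vertical axis) of each of 141 LacZ CpG sites against position in the reporter reference (bp, horizontal axis), 1 panel per line and 1 colour per tissue. In Dstn, levels differ between groups of neighbouring sites. Over the 24 libraries, 14 sites, such as position 150, have an SD of at most 6.12 points.

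LacZ and island levels came from the same knockout DNA and were compared over lines and over tissues. Over the 6 line means, Pearson's r was 0.155 (exact permutation p = 0.739) and Spearman's rho 0.314 (exact permutation p = 0.564). Rgcc had a LacZ level of 12.8% and an island level of 8.62%, and Dstn 61.3% and 4.08%. Without elevated sites, the knockout island level was 3.34% in Rgcc and 0.468% in Dstn. Over the 24 line-centred pairs, r was 0.268 (permutation p = 0.254) and rho 0.204 (permutation p = 0.397). Within Dstn, r was -0.853 (exact permutation p = 0.0486, adjusted p = 0.389 over 8 correlations, n = 6) and rho -0.6 (exact permutation p = 0.242). The Dstn relation rested on few tissues, since r was -0.423 (exact permutation p = 0.625) without the 2 farthest from the median island level. Within Ninj1, r was -0.0884 (exact permutation p = 0.838, n = 6) and rho 0.257 (exact permutation p = 0.658). Without the 2 farthest samples, r was -0.103 over lines, 0.149 over line-centred pairs and 0.575 within Ninj1 (exact permutation p = 0.375), and rho was 0 over lines and within Dstn, 0.0954 over line-centred pairs and 0.8 within Ninj1 (exact permutation p = 0.333).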

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

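The between-line test was planned, and the tests of explanations and the reading of the counts of other splits were set after the result was seen.

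The island difference varied between lines, with line accounting for 87.8% of its sum of squares (permutation p = 1e-05), and Lyplal1 and Rgcc had larger mean differences than the other 4. The test takes tissues of a line as independent, so a difference between animals or amplicons could give the same result. Chance cannot be read from the splits of Rgcc, whose 10 splits are too few for a share under 0.05. The real split gave 27 sites and the highest other split 0, so the real split was the only 1 of the 10 as large. For Rgcc, incomplete bisulfite conversion of knockout DNA would raise all sites about alike. Over the sites with a wild-type median under 5%, the 10th percentile of the gain was 3.43% of the median gain of called sites. That argues against a uniform failure over the whole island, but cannot tell apart a failure confined to a part of it. Of the 27 called sites, 25 lay on the lower-coordinate side. For Lyplal1 that value was 84.3%, over 23 sites with a wild-type median under 5%, whose gains ranged from 4.92 to 11.3 points. The 5 elevated sites, left out of that value, ranged from -0.101 to 15.5 points, so the gain was not even over the whole island. Incomplete conversion, or a minority of fully methylated molecules, may account for the gain at the 23 sites, and it stays open. Leaving out sites with a wild-type median of at least 5% argues against them as the whole source, since the gain was then 113.4% of its value in Rgcc and 101.9% in Lyplal1. With the rule on both genotypes' medians the gain was 1.60 points in Rgcc and 5.91 in Lyplal1, against 2.01 and 6.69 over all sites. Counting error at the lower depth of the Lyplal1 knockouts is also excluded, the smaller gain being 18.8 times the widest Wilson margin of the line's pooled levels. That margin takes sites on a read as independent; with all sites of a library erring together the widest margin of a level was 1.38 points, still below the smaller gain of 4.68, though a bottleneck of few template molecules was not tested. An effect of the targeted allele, the biological explanation the design names, stays open and untested.

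Wild-type liver of Arap had an island level of 3.08%, far from the other 4 wild-type tissues, the nearest of which was at 0.633%. Knockout liver was also the highest Arap knockout, at 2.24%. At position 108496701, liver had 12.3% in the knockout and 16.6% in wild type, against at most 2.34% in any other Arap library. The excess of liver over the other tissues correlated between genotypes across the 31 sites (r = 0.948), and sites are not independent replicates. Among 100 splits of the Arap libraries, 8 gave at least the 5 sites of the real one, so chance was not excluded. Other splits can keep the genotype contrast of most tissues, so this share cannot decide the question. The highest other split gave 27, as did exchanging only the liver libraries between the genotypes. Liver was the only Arap tissue with wild type above knockout, at a difference of -0.836 points. The difference was 0.688 in brain, 0.677 in heart, 0.226 in kidney and 0.271 in lung. The exchange therefore gave all Arap tissues the same direction. Of the 16 exchanges within tissues, 2 gave at least 5 sites, the real one included, and 16 are too few for a share under 0.05.

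Dstn lung had an island difference of 0.601 points, far above the next Dstn tissue, at 0.224. In all, 12 groups of tissues were examined for such distant values and 2 had one, and chance gives about 1 in 20. In Dstn and Ninj1, 94 of the 100 splits drawn could be fitted with the tissue term. In Dstn the real split gave 0 sites, so all 94 necessarily gave at least as many and the comparison cannot inform; the highest other gave 2. In Ninj1, 2 of 94 splits, the real one included, gave at least 5 sites, a share under 0.05, the highest other giving 7. The splits take libraries as independent, so they cannot tell a genotype effect from a difference between animals or amplifications. Of the 5 called sites, 3 were elevated sites, and the count was 1 without brain. Of the 32 exchanges within tissues only the real one gave 5, the highest other giving 2.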

How the results depend on the processing

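Leaving out elevated island sites (wild-type median of at least 5%) and near-constant LacZ sites was chosen after seeing the data. Across settings other than leaving out samples, 171 values kept their direction and their side of the threshold, 22 changed direction, 13 lost the threshold or had a lower count by over 1.5 times, and 5 gained it. Leaving out samples, 245 kept both, 8 changed direction, 11 lost the threshold or had a lower count by over 1.5 times, and 2 site counts rose, in Arap without liver (5 to 28) and Dstn without brain (0 to 1). The cause was not tested unless stated. The island difference over lines passed with the median over sites (1.49) and without elevated sites (1.74, or 1.65 at sites in every library). With the rule on both genotypes' medians these were 1.40 and 1.39. In single lines, direction changed in Arap with no coverage minimum (-0.328), in Ninj1 with pooled reads (-0.594) and in Rab32 with the median (0.294) and without elevated sites by either rule (0.272, or 0.281 at sites in every library), where fewer sites enter. The contrast of the island's 2 sides changed direction with no minimum (-0.414), 100 reads (-0.176), the median (-0.492), log2 odds (-0.0938), sites in every library (-0.0984) and without elevated sites (-0.440). LacZ against island level changed direction within lines with no minimum (-0.00261), and over lines rho did with the median (-0.371) and without elevated and near-constant sites (-0.200). Within Dstn r was 0.0315 with the median. Within Ninj1 r was 0.499 with no minimum, 0.0430 with 100 reads and 0.240 with sites in every library, and rho -0.600 with the median and -0.543 without elevated and near-constant sites.

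A difference of at least 10 points left 0 sites in Arap, 1 in Lyplal1, 2 in Ninj1, 1 in Rab32 and 1 in Rgcc, since most differences were smaller. Without a tissue term, Ninj1 had 3 sites and Rab32 0, and without its 13 elevated sites, among them 3 of the 5 called, Ninj1 had 3. Leaving out each sample in turn, the island difference ranged from 0.519 (without Lyplal1) to 1.91 over lines, LacZ against island r over lines from -0.131 to 0.456, within Ninj1 r from -0.774 to 0.460 and rho from -0.3 to 0.7, tissue shares from 6.54% to 30.1% for knockout and 9.99% to 23.2% for wild-type islands, and the contrast of sides from -0.211 to 0.318. Called sites ranged from 0 to 28 in Arap, 0 to 1 in Dstn, 1 to 6 in Ninj1 and 25 to 30 in Rgcc. The tests within single lines cannot pass after adjustment, whose lowest possible value is 0.0938, so their unchanged calls say nothing about stability. The 2-tissue lines Lyplal1 and Rab32 have no count of other splits. If reads were independent, the 95% counting margin of a level was at most 0.722 points with sites erring independently and 2.01 with sites erring together, both in Ninj1, and the number of template molecules was not measured.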

Other observations

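All tests in this part were chosen after the result was seen. Some LacZ sites varied little between libraries: 14 of 141 sites had an SD of at most 6.12 points over the 24 libraries, against at least 10.3 for each other site, with means from 31.9% to 78.1%. Of these, 11 were among the 2 outermost sites at an end of a stretch of covered sites, against 9 of the other sites, of which 118 lay elsewhere (Fisher's exact p = 6.82e-09). A candidate explanation is that mixed bases in the PCR primers, not the template, set these levels. Position 424, 1 of the 14, ran from 69.7% in Arap lung to 89.5% in Dstn kidney, a range that this explanation does not account for by itself. The primer sequences were not at hand, and no biological explanation was tested. Separately, islands had sites with a wild-type median of at least 5%, some of which differed between genotypes, while the other sites of a line had a median wild-type level of 0.414% to 0.793%; they numbered 8 of 78 in Dstn, 13 of 55 in Ninj1, 5 of 28 in Lyplal1, 4 of 40 in Rab32, 7 of 67 in Rgcc and 0 of 31 in Arap.

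LacZ levels differed between groups of neighbouring sites. In Dstn the group from 1823 to 2068 had 85.1% ± 26.0 and that from 2629 to 2896 had 17.3% ± 2.05 (SD, n = 6 tissues). The 6 groups, bounded by gaps and near-constant sites, explained 54.5% of the variance between sites of a library on average. All 126 rotations of the boundaries gave less, the highest 53.5%. Groups set apart by gaps would also do well if levels changed gradually with position, so the rotations cannot show steps. The near-constant sites were chosen from the same data. Amplification that favours methylated or unmethylated strands differently in each amplicon may contribute, which the rotations cannot decide. A gradient shared by lines cannot be told apart from chance order with 6 lines (Kendall's W = 0.311, permutation p = 0.0882).

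Among islands with at least 6 libraries, single libraries lay over 3 points above every other library of the line at 7 sites in Rgcc knockouts, 4 in Ninj1 knockouts, 1 in Dstn knockouts and 4 in Arap wild type, sites with a wild-type median of at least 5% left out. In Ninj1 spleen, positions 49283156, 49283373 and 49283379 had 5.06%, 5.28% and 5.17%, against at most 0.582%, 0.844% and 0.918% in any other Ninj1 library. In Dstn lung, position 143741075 had 5.75%, against at most 1.18% elsewhere in the line. The Rgcc sites were 5 in muscle and 2 in heart, such as position 79701326 with 7.80% in muscle against at most 2.67% elsewhere. Coverage was low at most of the Rgcc sites, 5 of the 7 having a library with 86 to 93 reads, and at the Ninj1 site with a library of 15. The 95% Wilson intervals of the highest and next library lay apart at 4 of the 7 Rgcc sites and 3 of the 4 Ninj1 sites. Counting error was not excluded at the others. Intervals that lie apart do not exclude it either, because the sites were picked for their gap and PCR reads are not independent molecules.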
